A study of Homo sapiens and Mus musculus with 43 samples.

How the data were processed

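RNA was sequenced from HEK293 cells, a human embryonic kidney cell line, and from liver and kidney of male C57BL/6J mice. The 43 libraries fall into 12 groups, taken from the submitters' labels. Per the labels' protocols, each library is a biological replicate, total RNA was isolated with column kits, and libraries were built and sequenced by BGI. The labels do not say whether same-numbered liver and kidney libraries come from 1 mouse.

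For HEK293 cells, the authors deposited raw counts, whole numbers of reads per gene symbol, for 37994 genes. For liver and kidney, the authors deposited expected counts, estimated read numbers that need not be whole. In these mouse tables the lowest value is 0.015 in place of 0, and 1.75% of kidney values and 0.99% of liver values are other fractions. The submitters' processing notes name DESeq2 1.42.1 and the genome builds GRCh38 and GRCm39. The aligner, the counting tool and the annotation are not given in the sources used here, and neither is the use of strand. Reads shared between near-identical or overlapping genes may therefore have been split in unknown ways, and counts of such genes are uncertain.

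The mouse values were rounded to whole numbers, which sets the fill value to 0. Each mouse table has 36930 lines, of which 49 repeat a symbol already listed. Of these, 47 were summed and 2 under a symbol that stands as a date were kept apart, leaving 36883 genes. The 25 symbols that stand as dates were kept under those names, as were 24 symbols of the HEK293 table that stand as whole numbers, and none is named in the text. No blank names were found. No mouse annotation was used here, so mouse genes are given by symbol. Human coordinates come from GENCODE version 29 on GRCh38, 1-based.

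Total counts per library ranged from 35494974 to 37533538 in HEK293 cells, from 31905426 to 35105317 in kidney and from 15816046 to 32270851 in liver. Shallower libraries give larger counting error for low genes, and intervals from counts cover counting error only. No 2 libraries held identical values. The lowest chi-square per degree of freedom between replicates of a group was 3.41 in HEK293 cells, 11.1 in kidney and 21.3 in liver, so every pair differed by more than sampling noise and each library was counted once.

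Differential expression was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the package's filter on low counts. The 24 HEK293 libraries entered 1 fit with a mean per treatment. Liver and kidney were fitted separately, and the difference between their responses was tested as an interaction over the joined 19 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed. All fold changes are log2 values. Their standard error (SE) was derived from the test, as the absolute log2 change over the square root of its F statistic. It is therefore approximate, least reliable for genes with a group near the floor, and the intervals of single genes between compounds rest on it. Levels are counts scaled to a common library size (CPM) after TMM scaling unless a share of the library total is named. Adjusted p-values of single genes in the text are from this edgeR test.

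Gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives not named below as added or run later. They hold textbook targets of XBP1s, of ATF6 and of PERK and ATF4, other response pathways, and markers of cell types that each tissue piece could contain. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry. Their p-values were adjusted over the lists and contrasts of a family. The number of list members that passed is given over all genes tested and adjusted over the list alone.

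Named genes had a standard symbol and a mean of at least 1 CPM. For IXA62 and thapsigargin in HEK293 cells and for each tissue, the 10 higher and 10 lower genes with the largest change were taken among those past the threshold whose CPM ranges did not overlap. For the other compounds and the contrasts between compounds, 3 in each direction were taken. Up to 4 members past the threshold were taken per list and comparison. The 11 genes XBP1, DNAJB9, SEC24D, SEC61B, HSPA5, PDIA4, DDIT3, ATF3, ASNS, BLOC1S1 and ERN1 were named whatever their values. Genes named outside this rule are marked as chosen after their values were seen. The result of 1 gene is not reported here.

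The steps were tested on simulated counts with known changes. In the simulated contrast of IXA62 with DMSO over 16701 genes, 58.2% of genes changed 1.5-fold and 86.4% of those changed 4-fold were recovered. The kidney simulation over 16267 genes recovered 31.3% and 97%. The liver simulation over 12851 genes recovered 0% at both sizes with 9 libraries. With 8 libraries and 12902 genes it recovered 1.5% and 72.7%, and the 18-library simulation of the tissue difference over 17561 genes recovered 3% and 53%.

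In kidney, samples of both arms that share a replicate number deviated together from their group means. The 5 correlations across genes ranged from 0.176 to 0.449, with a mean of 0.305 against -0.072 for samples of different number, and 1 of the samples correlated best with its own number. The arms hold different mice, so the pairing comes from the data, in which all 5 values exceeded 0.1, and the labels do not name what a number marks. Kidney results from a fit with the number as a block are therefore given beside those without it wherever they change a call, and the tissue difference has a fit with that block for the kidney libraries alone.

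Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, fits of 2 groups alone against DMSO, a replicate block, and each replicate left out. After seeing the data, robust fitting was added. Fits without the library labelled liver vehicle 1 and without the liver libraries of lower depth, the kidney block of the tissue difference, fits of 2 groups alone between compounds, the alternatives of the list tests against thapsigargin, and the alternatives of the fixed genes and list members in the contrasts between compounds were also run only then. No library was left out of the 9-library and 19-library fits.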

Results

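Gene expression was measured by RNA sequencing after exposure to compounds named IXA, which the study describes as activators of the IRE1/XBP1s arm of the unfolded protein response (UPR). IRE1 is a sensor of misfolded proteins in the endoplasmic reticulum (ER) that splices the mRNA of the transcription factor XBP1. The ATF6 and PERK arms are the other branches of the UPR. HEK293 cells received vehicle (DMSO), IXA21, IXA62, IXA76, IXA502, IXA554 or IXA624 at 10 µM, or thapsigargin (Tg) at 0.5 µM, for 6 h, with 3 libraries per group. Tg depletes ER calcium and activates all UPR arms. Mice received IXA62 at 50 mg/kg or vehicle by daily intraperitoneal injection for 7 days, and tissues were taken 4 h after the last injection. Kidney had 5 libraries per arm, and liver had 4 labelled vehicle and 5 labelled IXA62. The total count per library was 35494974 to 37533538 in HEK293 cells, 31905426 to 35105317 in kidney and 15816046 to 32270851 in liver.

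The first comparison asked which genes IXA62 changed in HEK293 cells. XBP1 itself (chromosome 22, 28794555 to 28800597) rose from 110 ± 4.24 to 241 ± 9.89 CPM (SD, n = 3 each), a log2 change of 1.13 ± 0.05 (SE). DNAJB9 (chromosome 7, 108569568 to 108574850), an ER co-chaperone and XBP1s target, rose by 1.56 ± 0.10, and SEC24D (chromosome 4, 118722823 to 118838683), a coat protein of ER-to-Golgi vesicles, by 1.11 ± 0.07. The ER chaperone gene HSPA5 (chromosome 9, 125234853 to 125241330) rose by 0.83 ± 0.05, PDIA4 by 0.61 ± 0.05 and SEC61B by 0.38 ± 0.07. DDIT3, which encodes the transcription factor CHOP, rose by 0.94 ± 0.16, from 2.43 to 4.66 CPM. ATF3 rose by 0.65 ± 0.08 and ASNS by 0.31 ± 0.05. ERN1, which encodes IRE1, was at -0.05 ± 0.14 and did not pass (edgeR adjusted p = 0.851).

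Of the 37 tested XBP1s targets, 28 rose with IXA62, none fell and 29 rose when adjusted over the list alone. The list test gave a camera adjusted p of 3.28e-29, and 0.000151 with an estimated correlation. In the ATF6 list, 10 of 12 rose, led by HERPUD1 at 1.20 ± 0.05, a component of ER-associated degradation (11 adjusted over the list alone; camera adjusted p = 4.43e-24). The PERK and ATF4 list had 14 members higher and 2 lower of 24, or 15 and 4 adjusted over the list alone, among them CHAC1 at 1.10 ± 0.16 and DDIT4 at 0.91 ± 0.11. Its camera adjusted p of 7.42e-08 became adjusted p = 0.0518 with an estimated correlation. In the list of heat-shock factor 1 targets, 7 rose and 1 fell of 14 (8 and 2 adjusted over the list alone; camera adjusted p = 2.28e-05, and 0.0233 with an estimated correlation). HSPA1A at 1.01 ± 0.06 and HSPA1B at 1.00 ± 0.07 led it, and these near-identical genes may share reads. In the list of transcripts cut by IRE1 (RIDD), 3 rose and 2 fell of 8 in both counts (camera adjusted p = 0.661), with BLOC1S1, a known RIDD target, higher by 0.50 ± 0.08.

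Outside the UPR lists, and among genes named by the rule with a mean of at least 1 CPM, the largest rise was that of RARB (chromosome 3, 25174332 to 25597932), a retinoic acid receptor, at 2.19 ± 0.13, from 2.27 ± 0.30 to 10.4 ± 0.92 CPM (SD, n = 3). CYP26A1, a retinoic acid hydroxylase, rose by 1.27 ± 0.15 and RXRG, a retinoid X receptor, by 1.41 ± 0.29. CALCB, TRIM46, CDH1, SLC16A14 and LY6G6D rose by 1.28 to 1.46. DGAT2 (chromosome 11, 75759512 to 75801535), which makes triglyceride, fell from 7.41 ± 1.00 to 0.97 ± 0.23 CPM, a log2 change of -2.93 ± 0.24. ETV5, a transcription factor, changed by -2.33 ± 0.39 and BCAM by -1.74 ± 0.15. CTGF and CYR61, both targets of the YAP pathway, changed by -2.25 ± 0.19 and -1.38 ± 0.11. PKD2L2, APOE, PTH1R, INS-IGF2 and HIST2H4B also fell, by log2 changes of -1.33 to -1.57, and the last pair overlap or nearly match other genes, so their counts are uncertain. In all, 4071 of 16701 genes passed, 2052 higher and 2019 lower, and 241 changed at least 2-fold.

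The second comparison set the other IXA compounds against DMSO. XBP1 rose by 1.09 to 1.30 and SEC24D by 1.05 to 1.32 over the 6 compounds, and DNAJB9 rose by 1.13 ± 0.10 with IXA624 to 1.68 ± 0.10 with IXA502. HSPA5 rose by 0.73 ± 0.05 with IXA624 to 1.08 ± 0.05 with IXA502. DDIT3 rose with 5 of them, by 0.51 to 1.07, and with IXA76 it was at 0.42 ± 0.16 (edgeR adjusted p = 0.0787). BLOC1S1 rose with IXA21, IXA62 and IXA624 and did not pass with IXA76, IXA502 or IXA554. Some of these calls rested on single libraries. With IXA21, DDIT3 lost its call without DMSO replicate 2 (adjusted p = 0.0609), DMSO replicate 3 (0.0855) or IXA21 replicate 2 (0.0987), and BLOC1S1 without DMSO replicate 2 (0.0778) or IXA21 replicate 1 (0.0845). With IXA76, DDIT3 passed without IXA76 replicate 3 (0.0244, with alternatives from 0.0244 to 0.304).

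Of the 37 XBP1s targets, 27 rose with IXA21, 32 with IXA76, 32 with IXA502, 30 with IXA554 and 28 with IXA624. Adjusted over the list alone these were 31, 33, 34, 32 and 29. Camera adjusted p ranged from 5.59e-25 to 3.55e-52, and from 0.000314 to 1.35e-05 with an estimated correlation. Of the 12 ATF6 targets, 11 rose with each of these 5 compounds, and 11 adjusted over the list alone, where IXA624 also had 1 lower. Of the 24 PERK and ATF4 genes, the numbers higher and lower were 11 and 4 with IXA21, 10 and 2 with IXA76, 16 and 2 with IXA502, 10 and 2 with IXA554 and 15 and 3 with IXA624. Adjusted over the list alone they were 11 and 4, 13 and 2, 16 and 2, 14 and 3, and 15 and 3. Camera called this list higher for all 5, and the call held with an estimated correlation for IXA502 (adjusted p = 0.00553) and IXA624 (0.0204) but not for IXA21 (0.4), IXA76 (0.197) or IXA554 (0.114). The RIDD list did not pass with any of the 7 treatments (camera adjusted p from 0.318 to 0.926). In the fit with a replicate block, camera also called lists of other pathways. The cell cycle list was higher with every IXA compound (camera adjusted p from 0.000158 to 0.0314). The AHR list was lower with IXA76, IXA554 and IXA624 (0.00605, 0.00487 and 0.0413). NRF2 targets were higher with IXA76, IXA502, IXA554 and Tg (0.0121 to 0.0413), and p53 targets with IXA554 and Tg (0.0343 and 0.0227). That fit had no test with an estimated correlation.

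RARB rose by 1.70 to 2.56, and ETV5 fell, with log2 changes from -2.90 to -1.87. DGAT2 changed by -2.61 with IXA21 and by -2.53, -2.83 and -2.63 with IXA76, IXA502 and IXA554, and by -1.78 with IXA624. HSPA1A rose by 0.80 ± 0.06 with IXA21 to 1.63 ± 0.06 with IXA502. DHRS3, which reduces retinaldehyde, rose by 1.89 ± 0.24 with IXA21. The largest changes with IXA624 were in NBL1 and MINOS1-NBL1, which overlap, and their summed level was 8.71 ± 0.55 CPM against 7.16 ± 0.68 in DMSO (SD, n = 3), so neither is described as changed. PPAN-P2RY11, also an overlapping gene, was at -1.77 ± 0.32 with IXA76.

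Genes of cholesterol synthesis fell with IXA76, 10 of 15 lower and none higher, with INSIG1 at -0.51 ± 0.07 and HMGCS1 at -0.47 ± 0.06 (11 lower adjusted over the list alone; camera adjusted p = 2.01e-10, and 0.000116 with an estimated correlation). With IXA554, 8 fell, or 9 adjusted over the list alone (camera adjusted p = 7.64e-06, and 0.00226 with an estimated correlation), and 5 fell with IXA624, or 6 (0.00851, and 0.0381). With IXA502, 5 fell, or 6 with 1 higher (camera adjusted p = 0.0355, and adjusted p = 0.0834 with an estimated correlation). With IXA62, 1 rose and 3 fell in both counts, and the list did not pass (camera adjusted p = 0.706), with a median of 0.05 where its mean (-0.02) and the test pointed down. The numbers of genes past the threshold were 3727 for IXA21, 2932 for IXA76, 3173 for IXA502, 2628 for IXA554 and 4239 for IXA624.

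Tg was compared with DMSO as a general ER stressor. HERPUD1 rose by 3.65 ± 0.05, DDIT3 by 3.67 ± 0.15, CHAC1 by 3.45 ± 0.15 and HSPA5 by 2.77 ± 0.05, from 586 ± 17.7 to 3986 ± 384 CPM (SD, n = 3). LBH rose by 3.82 ± 0.26, and GEM, MIOX, SIAH1 and FICD rose by 2.33 to 2.77. DGAT2 changed by -3.44 ± 0.25, BCAM by -2.38 ± 0.16 and the immediate early gene EGR1 by -1.73 ± 0.39. Of the XBP1s targets 31 of 37 rose, or 34 adjusted over the list alone, with all 12 ATF6 targets in both counts. Of the PERK and ATF4 list 22 of 24 rose in both counts. Each of these lists kept its call with an estimated correlation, at adjusted p of 1.91e-05, 7.64e-08 and 1.35e-05. HSF1 targets had 6 lower and 1 higher, both ways of adjusting (camera adjusted p = 0.0476, and 0.246 with an estimated correlation). In all, 4745 genes passed, 2485 higher and 2260 lower.

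**Figure D1:**
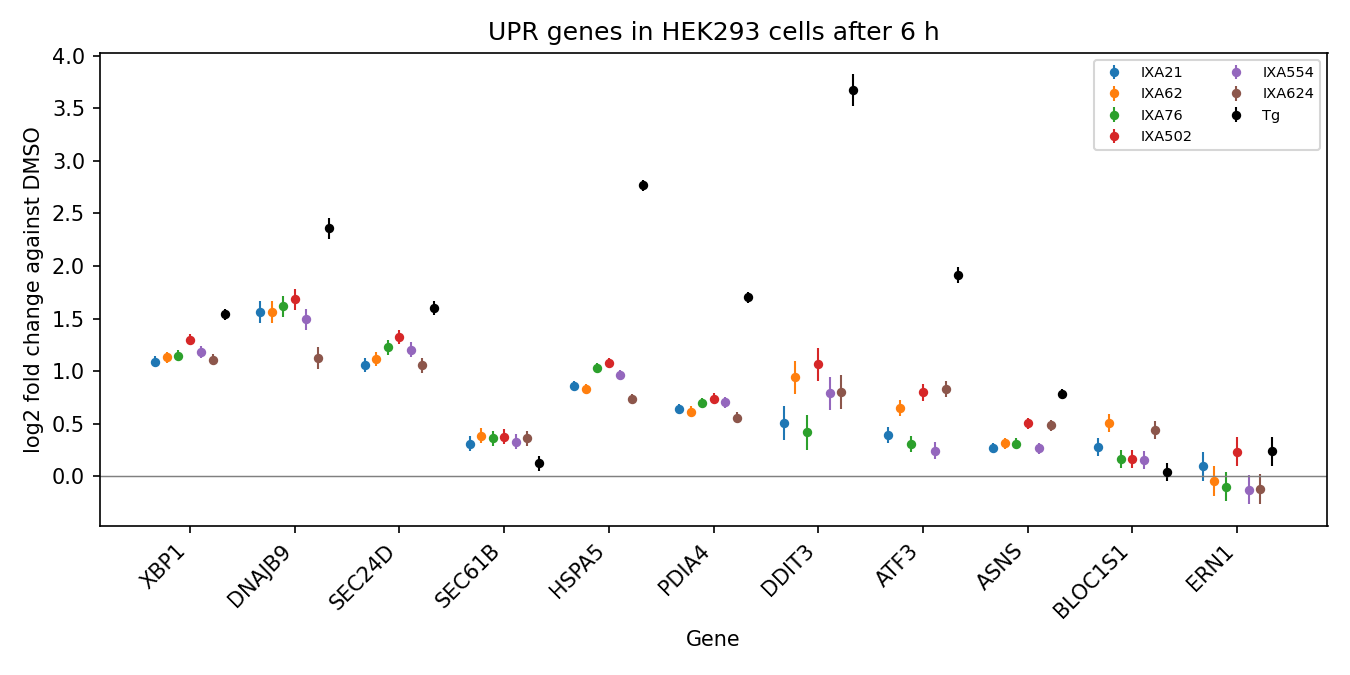
Log2 fold change against DMSO (vertical axis) of 11 UPR genes (horizontal axis) in HEK293 cells after 6 h, with 1 point per compound and error bars of 1 SE derived from the F-test (n = 3 libraries per group). The Tg points for HSPA5 (2.77) and DDIT3 (3.67) lie above those of the 6 IXA compounds, whose HSPA5 values lie between 0.73 and 1.08.

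The compounds were then tested against Tg in the same fit, although Tg was given at 0.5 µM and the IXA compounds at 10 µM. The 12 ATF6 targets were lower with IXA62 than with Tg, all 12 of them in both ways of adjusting, by a median of -1.11 (camera adjusted p = 2.4e-204, and 2.93e-09 with an estimated correlation). In the PERK and ATF4 list 23 of 24 were lower, or 24 adjusted over the list alone, by a median of -0.80 (adjusted p = 2.69e-07 with an estimated correlation). For the XBP1s list 12 were lower and 2 higher, or 15 and 2 adjusted over the list alone, with a median of -0.12 (camera adjusted p = 5.98e-16, and 0.00181 with an estimated correlation). HSPA5 was at -1.93 ± 0.05 against Tg, DDIT3 at -2.73 ± 0.14, DNAJB9 at -0.80 ± 0.09 and XBP1 at -0.41 ± 0.05. The HSF1 list was higher with IXA62, with 7 members higher and none lower, or 8 and none adjusted over the list alone (adjusted p = 3.3e-05 with an estimated correlation). For the other 5 compounds the XBP1s median lay between -0.13 and -0.02 and the ATF6 median between -1.19 and -0.96. The XBP1s call against Tg was lost for IXA502 with an estimated correlation (adjusted p = 0.0575).

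At the matched dose of 10 µM and time of 6 h, IXA62 was tested against each other IXA compound. Among the genes lower with IXA62 than with IXA502 were HSPA1A at -0.61 ± 0.06, HSPA5 at -0.24 ± 0.05 (95% interval -0.34 to -0.14), HERPUD1 at -0.24 ± 0.05, CTH, an enzyme of cysteine synthesis, at -0.52 ± 0.09 and STC2 at -0.43 ± 0.07, while the developmental gene EYA1 was higher at 1.32 ± 0.21. DDIT3 and ATF3 did not pass in this contrast (edgeR adjusted p = 0.698 and 0.271), and neither did the HSF1 list (camera adjusted p = 0.148), and the camera calls of the ATF6 and the PERK and ATF4 lists as lower were lost with an estimated correlation (adjusted p = 0.217 and 0.3). Cholesterol genes were higher with IXA62 than with IXA76, with INSIG1 at 0.61 ± 0.07 and SQLE at 0.32 ± 0.05, and SYTL5 was lower at -1.66 ± 0.22. ZCCHC12 was lower than with IXA554 at -0.86 ± 0.12, and HERPUD1 was higher than with IXA624 at 0.39 ± 0.05. Each of these calls held without any 1 library of its contrast. Fitted on the 2 groups alone, a fit added after seeing the data, HSPA5, CTH and HERPUD1 against IXA502 and SQLE against IXA76 lost their calls (edgeR adjusted p = 0.053, 0.053, 0.0864 and 0.107) and the others kept them. ATF4 at 0.23 ± 0.04, STAB1 at 0.73 ± 0.13 and the mitochondrial tRNA gene TRNM at 1.21 ± 0.18 were higher than with IXA21 (edgeR adjusted p = 0.0335, 0.0341 and 0.00257), and TRNM was named after its value was seen. ATF4 and STAB1 lost their calls without IXA21 replicate 1, 2 or 3 or IXA62 replicate 2 or 3 (adjusted p = 0.0614, 0.307, 0.391, 0.174 and 0.295 for ATF4 and 0.199, 0.248, 0.391, 0.174 and 0.295 for STAB1, in that order of libraries), and with the 2 groups alone (0.0975 and 0.0868). That fit of 2 groups called 0 genes, so TRNM lost its call in it as well.

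Other UPR genes differed less firmly. HSPA5 was lower with IXA62 than with IXA76 by -0.20 (95% interval -0.29 to -0.10, edgeR adjusted p = 0.0373), a call lost without IXA62 replicate 2 or 3 or IXA76 replicate 1 or 2 (0.199, 0.173, 0.13 and 0.0684 in that order). ATF3 was higher than with IXA76 by 0.34 (95% interval 0.18 to 0.49, edgeR adjusted p = 0.0238), a call lost without IXA62 replicate 2 or 3 or IXA76 replicate 1 or 2 (0.0993, 0.169, 0.0681 and 0.0708 in that order). ASNS differed from its level with IXA502 by -0.19 (-0.29 to -0.09, edgeR adjusted p = 0.0258), a call lost without IXA62 replicate 1, 2 or 3 or IXA502 replicate 1, 2 or 3 (0.0745, 0.1, 0.0526, 0.0544, 0.0661 and 0.0695). BLOC1S1 was higher by 0.34 (0.17 to 0.51) than with IXA502 (edgeR adjusted p = 0.0161) and than with IXA76 (0.0392). The call against IXA502 was lost without IXA62 replicate 2 or 3 or IXA502 replicate 2 (0.0975, 0.0567 and 0.105), and that against IXA76 without IXA62 replicate 2 or 3 or IXA76 replicate 1, 2 or 3 (0.216, 0.204, 0.0667, 0.0677 and 0.097). ATF3 was higher than with IXA554 by 0.40 (0.25 to 0.56, adjusted p = 0.01), a call lost without IXA62 replicate 2 or 3 or IXA554 replicate 3 (0.0563, 0.0649 and 0.087). DNAJB9 was higher than with IXA624 by 0.43 (0.24 to 0.62, edgeR adjusted p = 0.0449), a call lost with RLE size factors (0.0543) and without IXA62 replicate 1 or 2 or IXA624 replicate 1, 2 or 3 (0.0527, 0.179, 0.157, 0.134 and 0.0844 in that order). With the 2 groups alone the calls of this paragraph were lost for HSPA5, ATF3 and BLOC1S1 against IXA76 (0.245, 0.163 and 0.245), ASNS and BLOC1S1 against IXA502 (0.144 and 0.115) and DNAJB9 against IXA624 (0.0727), and kept for ATF3 against IXA554. XBP1 did not pass against any of the 5 by edgeR, with intervals that ran from -0.27 at the lowest to 0.15 at the highest. The interval against IXA502 (-0.27 to -0.06) was wholly negative. Against IXA502 the edgeR adjusted p of XBP1, 0.0593, became 0.0259 with DESeq2 and 0.0222 without IXA502 replicate 1, with alternatives from 0.0222 to 0.208.

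The mean of the XBP1s list with IXA62 less that with IXA21 was 0.02 (95% interval -0.03 to 0.07), with IXA76 -0.07 (-0.12 to -0.02), with IXA502 -0.07 (-0.12 to -0.02), with IXA554 -0.04 (-0.09 to 0.01) and with IXA624 0.03 (-0.02 to 0.08). The camera calls of this list against IXA76 and IXA502 were lost with an estimated correlation (adjusted p = 0.217 and 0.29). The cholesterol synthesis list was higher with IXA62 than with IXA76 by a mean of 0.24 (0.20 to 0.28, adjusted p = 6.41e-06 with an estimated correlation), with 7 of 15 higher or 11 adjusted over the list alone. It was also higher than with IXA554 by 0.16 (0.12 to 0.20, adjusted p = 0.000204), with 3 higher or 9.

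In all, 3 genes differed from IXA21, all higher with IXA62, 206 from IXA76 (60 higher and 146 lower), 766 from IXA502 (356 and 410), 58 from IXA554 (24 and 34) and 32 from IXA624 (26 and 6). Fitted on the 2 groups alone, edgeR called 0 against IXA21 (1362 at an unadjusted p under 0.05), 3 against IXA76, 38 against IXA502, 25 against IXA554 and 31 against IXA624. Single libraries moved these counts as well. The 3 against IXA21 became 102 without IXA62 replicate 1, and 1 without IXA62 replicate 2 or 3 or IXA21 replicate 1 or 3. The 206 against IXA76 became 911, 14 and 13 without IXA62 replicates 1, 2 and 3, and 98 and 129 without IXA76 replicates 1 and 2. The 766 against IXA502 became 327 and 416 without IXA62 replicates 2 and 3, and 386 and 268 without IXA502 replicates 1 and 2. The 58 against IXA554 became 313, 2 and 15 without IXA62 replicates 1, 2 and 3, and 25, 38 and 18 without IXA554 replicates 1, 2 and 3. The 32 against IXA624 became 353, 6 and 11 without IXA62 replicates 1, 2 and 3, and 4, 8 and 7 without IXA624 replicates 1, 2 and 3. DESeq2 called 31 against IXA21, 530 against IXA76, 268 against IXA554 and 186 against IXA624.

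Calls against DMSO overlapped between compounds. IXA62 and Tg shared 2752 genes called in the same direction, 1428 higher and 1324 lower, against 305 and 273 for independent lists, and 17 were called in opposite directions. The fold changes of the pair correlated across genes at 0.671, where unchanged groups simulated against shared controls gave 0.501, and genes are not independent replicates. The covariance was 0.149 against a simulated 0.0321. Simulated groups shared 0 calls by the edgeR test. Unchanged groups yield few calls at this threshold, so that count is no test of the overlap. With 3 DMSO libraries the controls could not be split, so part of the excess may come from the shared controls.

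In kidney, genes of the amino acid response rose with IXA62. Asns, which makes asparagine, rose from 5.30 ± 1.01 to 92.6 ± 35.5 CPM (SD, n = 5 each), a log2 change of 4.12 ± 0.32 (SE). Chac1, which degrades glutathione, rose by 6.27 ± 0.57, Trib3, a pseudokinase induced by ATF4, by 5.56 ± 0.63, and the folate enzyme gene Mthfd2 by 3.89 ± 0.36. For Chac1, vehicle replicate 3 held 96 of the 171 vehicle counts. Atf3 rose by 4.98 ± 0.75, Ddit3 by 2.99 ± 0.40, Slc7a5, an amino acid transporter, by 3.07 ± 0.38 and Aldh18a1 by 2.95 ± 0.26. The level of Atf3 was 35.3 CPM in IXA62 replicate 4 and 0.793 to 13.4 in the other treated kidneys. Fgf21, an ATF4-induced hormone, had 12 counts over the vehicle libraries and 1879 over the treated ones, a ratio of 160 (95% interval of counting error alone 91.3 to 310). That interval leaves out the spread between mice, and the treated counts ran from 14 to 668. Vehicle replicate 3 held 11 of the 12, and without it the ratio was 1530 against 1 count. Bhlha15, an XBP1s target in secretory cells, had 2 and 640 counts, a ratio of 327 (90.1 to 2700 by counting error alone). Without vehicle replicate 5, which held both vehicle counts, Bhlha15 was at least 175-fold higher against a floor of 3 counts over the group. Of the PERK and ATF4 list 17 of 26 rose and none fell, or 21 adjusted over the list alone (camera adjusted p = 1.69e-73, and 0.0112 with an estimated correlation).

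UPR targets of the ER rose as well. Dnajb9 rose by 2.20 ± 0.19, Sec24d by 1.63 ± 0.18, Hspa5 by 0.67 ± 0.12 and Pdia4 by 0.55 ± 0.11. Xbp1 was at 0.36 ± 0.17 (edgeR adjusted p = 0.468), Sec61b at 0.43 ± 0.12 (0.14), Bloc1s1 at -0.27 ± 0.17 (0.633) and Ern1 at 0.02 ± 0.25 (0.991). Of the XBP1s targets 14 of 36 rose, or 30 adjusted over the list alone, with Syvn1 at 0.94 ± 0.12 and Ficd at 1.13 ± 0.17 (camera adjusted p = 1.24e-49, and 0.0112 with an estimated correlation). In the ATF6 list 7 of 12 rose, or 8 adjusted over the list alone, including Manf at 1.28 ± 0.15 and Herpud1 at 1.19 ± 0.12 (camera adjusted p = 3.03e-26, and 0.0244 with an estimated correlation).

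Among genes that fell in kidney, the serpin genes Serpina1a to Serpina1e were lower by log2 changes of -1.41 to -1.26, and these 5 close paralogs may share reads. Scd1, a fatty acid desaturase, changed by -1.20 ± 0.23 and Zmynd12, a zinc finger gene, by -0.95 ± 0.17. The red cell list had 5 of 6 higher, in both ways of adjusting, with Alas2, the heme synthesis gene of red cells, at 1.33 ± 0.24 (camera adjusted p = 2.19e-12, adjusted p = 0.0779 with an estimated correlation). Camera also called the hepatocyte list, which holds Serpina1a, lower (adjusted p = 9.47e-05, and adjusted p = 0.155 with an estimated correlation) and the proximal tubule list lower (0.0158, and adjusted p = 0.431 with an estimated correlation). It called the distal convoluted tubule list (0.0177, and adjusted p = 0.431 with an estimated correlation) and the fibroblast list (0.0456, and adjusted p = 0.64) higher. The circadian gene Arntl rose by 1.26 ± 0.18. In all, 214 of 16267 genes passed, 189 higher and 25 lower, and with the replicate number as a block 347 passed, 260 higher and 87 lower, of which 212 were shared. The block also called the gluconeogenesis, collecting duct and renin-angiotensin lists lower (camera adjusted p = 0.0346, 0.0357 and 0.0333). In that fit the immediate early (camera adjusted p = 1.13e-05), metallothionein (0.00202) and p53 (0.00542) lists were called higher and the lipogenesis list (0.000745) lower. The blocked fit was not tested with an estimated correlation. DESeq2 called 448. Without vehicle replicates 1 to 5 in turn the count was 108, 94, 137, 117 and 142, and without IXA62 replicates 2 to 5 it was 524, 95, 115 and 87.

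Some kidney calls rested on single libraries. Hspa5 did not pass without vehicle replicate 2 (adjusted p = 0.0535) or 4 (0.0573) or IXA62 replicate 3 (0.0553) or 5 (0.061). Pdia4 did not pass without vehicle replicates 1 to 5 in turn (0.0537, 0.0625, 0.0676, 0.0999 and 0.0604) or IXA62 replicates 3 to 5 (0.0757, 0.0818 and 0.101). Scd1 lost its call without vehicle replicate 2 (0.0588) or 4 (0.0509) or IXA62 replicate 3 (0.0774) or 5 (0.0647), and Zmynd12 without vehicle replicate 2 (0.052) or IXA62 replicate 3 (0.0501). Alas2 lost it without vehicle replicate 2 (0.0563) or 4 (0.0509). Each other kidney gene given as higher or lower passed without any 1 library.

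**Figure D2:**
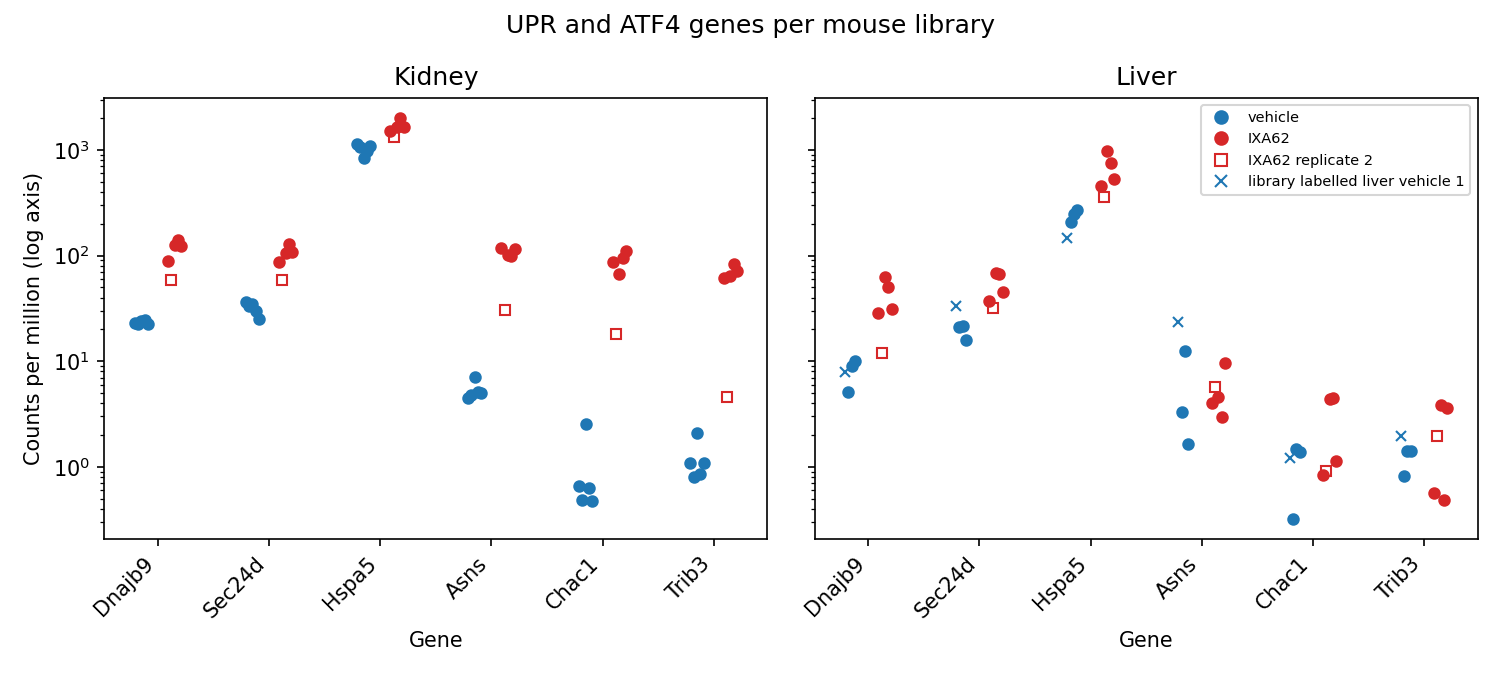
CPM on a log axis (vertical) for 6 genes (horizontal) in each kidney library (left) and liver library (right), with vehicle in blue and IXA62 in red. An open square marks IXA62 replicate 2 and a cross marks the library labelled liver vehicle 1. Kidney Asns lies between 4.52 and 7.06 in vehicle and between 30.6 and 117 in IXA62 libraries.

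In liver, the library labelled liver vehicle 1 held little liver RNA. Its albumin (Alb) level was 13.5 CPM of the library total, against 70199 to 92208 in the other 3 vehicle libraries, while the fat cell genes Adipoq and Cfd stood at 1814 and 13222, against at most 0.638 and 3.79 in the other 8 livers. Values are therefore given with and without it. The treated libraries IXA62 replicate 3 and 4 were shallower, at 17329293 and 15816046 counts, and had 37.8 and 34.3 CPM of the nuclear RNA Malat1, against 76.1 to 190 in the 7 other libraries.

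**Figure D3:**
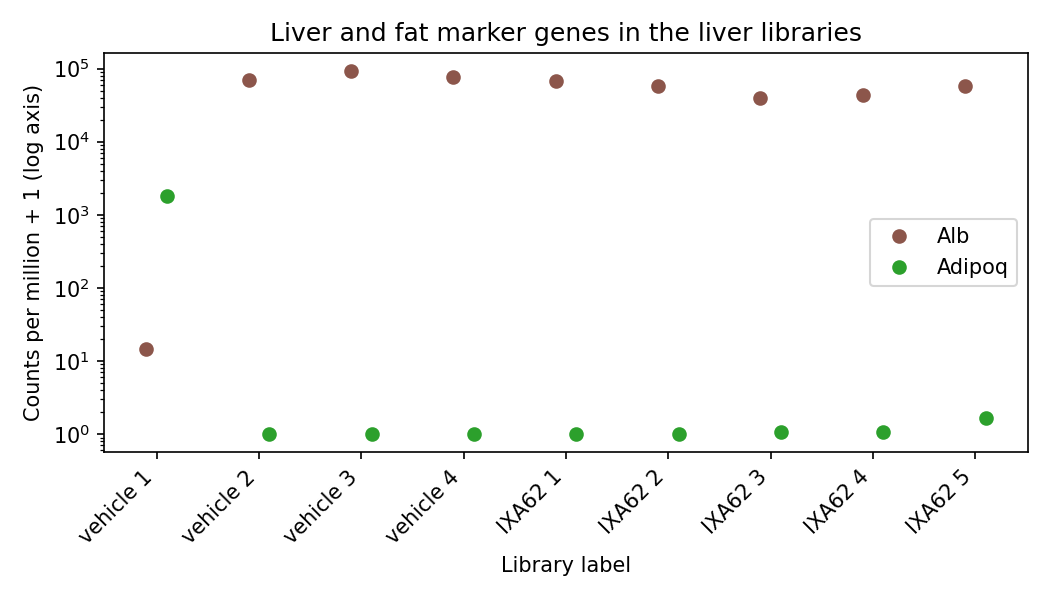
CPM of the library total plus 1, on a log axis (vertical), of the liver gene Alb and the fat gene Adipoq in each of the 9 libraries labelled liver (horizontal). The library labelled vehicle 1 has Alb at 13.5 and Adipoq at 1814 CPM before the 1 is added.

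Over the 8 other livers, Dnajb9 was at 2.17 ± 0.45 with IXA62 (30.9 ± 16.3 against 6.86 ± 2.17 CPM, SD, n = 5 and 3), Sec24d at 1.33 ± 0.28, Hspa5 at 1.33 ± 0.30 and Manf at 1.37 ± 0.27. Manf was named after its value was seen. Among the other fixed genes, Sec61b was at 0.99 ± 0.31, Pdia4 at 0.53 ± 0.22, Xbp1 at 0.24 ± 0.32, Bloc1s1 at 0.23 ± 0.23 and Ern1 at 0.04 ± 0.41. None of these genes passed over all genes tested (edgeR adjusted p of 0.304 to 0.98), while adjusted over the list alone 20 of 35 XBP1s targets and 8 of 12 ATF6 targets rose. With all 9 libraries, 9 and 5 rose adjusted over the list alone and Dnajb9 was at 2.19 ± 0.46. With 8 libraries Dnajb9 passed by DESeq2 (adjusted p = 0.000243), with no low-count filter (0.0273) and without IXA62 replicate 2 (0.0272), with alternatives from 0.000243 to 0.95, and Sec24d and Hspa5 passed by DESeq2 (0.00142 and 0.003, with alternatives up to 0.95). With 9 libraries DESeq2 called Dnajb9 (0.00836) and Hspa5 (0.046), with alternatives up to 0.706. The XBP1s list was higher by camera (adjusted p = 1.06e-15 with 9 libraries and 1.3e-23 with 8), and adjusted p = 0.449 and 0.257 with an estimated correlation. Bhlha15 had 0 counts over the 3 vehicle livers other than vehicle 1 and 159 over the treated ones, at least 39.6-fold higher against a floor of 3 counts over the group, and at least 26-fold without vehicle replicate 2 or 3. IXA62 replicate 2 had 0 counts, as those vehicle livers did, and the other treated livers had 27 to 68.

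The amino acid response genes did not pass in liver. Asns was at -0.11 ± 0.55 and Ddit3 at 0.48 ± 0.38 with 8 libraries. The Asns value leaned on vehicle replicate 3, at 12.5 CPM scaled over 9 libraries, against 3.27 and 1.63 in vehicle replicates 2 and 4. Treated livers lay between 2.97 and 9.6 on that scale. Of 21 tested PERK and ATF4 genes none rose adjusted over the list alone (camera adjusted p = 0.161 with 8 libraries, and 0.578 with 9). With 9 libraries the median of this list (0.23) and the test pointed up and its mean (-0.09) down. Cyp2b10, a cytochrome P450 induced through the receptor CAR, was at 4.91 ± 0.83 with 8 libraries and 5.31 ± 1.15 with 9, and 4 of 20 genes of the CAR and PXR list rose adjusted over the list alone with 8 and 1 with 9. Srebf1, Scd1, Fasn, Elovl5 and Acacb, all of fatty acid synthesis, fell adjusted over the list alone, with Elovl5 at -1.08 ± 0.25, and with 9 libraries 3 of 13 fell. These genes and Cyp2b10 were named for liver after their values were seen. The CAR and PXR and the lipogenesis lists passed by camera with 8 libraries (adjusted p = 0.00145 and 1.82e-06, each with adjusted p = 0.257 with an estimated correlation) and with 9 (2.65e-06 and 0.00574, each with adjusted p = 0.449).

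With 8 libraries camera called the hepatocyte (adjusted p = 0.000776), periportal hepatocyte (8.57e-06), cholangiocyte (0.0328), PPARA (0.00287) and cholesterol synthesis (8.57e-06) lists lower and the acute phase list (0.00127) higher, each a call then lost (adjusted p from 0.257 to 0.405 with an estimated correlation). Adjusted over the list alone, 1 hepatocyte and 3 periportal genes fell. With 9 libraries the hepatocyte list was called higher (0.00801), as was the acute phase list (3.76e-05), and the fibroblast (0.000151), endothelial (0.011) and mesothelium (0.00801) lists lower, each a call lost as well (adjusted p from 0.449 to 0.645 with an estimated correlation). Adjusted over the list alone, 4 fibroblast genes and 1 mesothelium gene fell. The hepatocyte list was called in opposite directions with and without the library labelled liver vehicle 1. No gene passed over all genes by edgeR, where 1470 of 12851 had an unadjusted p under 0.05 with 9 libraries and 1125 of 12902 with 8, and DESeq2 called 13 and 131. Without IXA62 replicate 2 edgeR called 1 with 9 libraries and 19 with 8, and with no low-count filter it called 13 with 8.

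The last comparison tested whether the response differed between tissues. Without the library labelled liver vehicle 1, 14 of 17561 genes passed by edgeR, 13 with a lower response in liver and 1 with a higher one. With the kidney number as a block for the kidney libraries, a fit added after seeing the data, 1 passed, Eif4ebp1, named after its value was seen, at -1.96 ± 0.25 (edgeR adjusted p = 0.0142), with 1440 at an unadjusted p under 0.05. Among the 13 were Asns at -4.31 ± 0.63, Atf5, an ATF4-induced transcription factor, at -2.86 ± 0.46 and Chac1 at -5.32 ± 0.91, all liver minus kidney. With this block Asns was at -4.20, Atf5 at -2.69 and Chac1 at -5.39, each with an adjusted p of 0.0502. Without it, Asns and Atf5 lost their calls without liver vehicle replicate 3 (adjusted p = 0.0808 and 0.0812) and kept them without each other single library. Chac1 lost its call without liver vehicle replicate 3 (0.144) or 4 (0.0694), kidney vehicle replicate 1, 2, 4 or 5 (0.0636, 0.0712, 0.0636 and 0.0658) or kidney IXA62 replicate 1, 4 or 5 (0.0553, 0.0552 and 0.0615). The PERK and ATF4 list was lower in this difference with 19 and with 18 libraries (adjusted p = 0.0293 and 0.0237 with an estimated correlation, and 0.0124 and 0.0107 with the kidney block), with 21 and 14 of 26 lower adjusted over the list alone. Dnajb9 was at -0.10 ± 0.46. The XBP1s list, which camera called higher at adjusted p = 0.0113 with 19 and 0.041 with 18, had adjusted p = 0.418 and 0.646 with an estimated correlation, and with 19 its mean (-0.07) pointed down where its median (0.04) and the test pointed up.

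With all 19 libraries no gene passed by edgeR, with 2961 of 17382 at an unadjusted p under 0.05 and 117 called by DESeq2. That count of 0 became 14, 10, 7 and 19 without liver vehicle replicates 1 to 4, 11 without kidney IXA62 replicate 2, and 1 without liver IXA62 replicate 1 or 4 or kidney vehicle replicate 3. The 18-library count of 14 became 9 and 0 without liver vehicle replicates 2 and 3, 35 and 22 without liver IXA62 replicates 2 and 5, and 28 without kidney IXA62 replicate 2. It became 5 without kidney vehicle replicate 1, 2 or 5 or kidney IXA62 replicate 4 or 5, and 6 without kidney vehicle replicate 4 or kidney IXA62 replicate 1 or 3. DESeq2 called 124 with 18 libraries.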

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

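All tests of explanations in this part, the other splits included, were chosen after the results they bear on were seen, and so were the fits without the library labelled liver vehicle 1. Of 134 values tested for a sample far from the rest of its group, 21 were found, and chance gives about 1 in 20.

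The library labelled liver vehicle 1 stood apart from the other vehicle livers in Alb (3.67 CPM after TMM scaling), the mean log2 CPM of the hepatocyte list (-0.482), Serpina1a (0.329 CPM), Serpina1d (0.388), Serpina1b (0.54), Scd1 (2600), Mthfd2 (1.22) and Aldh18a1 (4.52). Fat left on a piece of liver is argued against, since Alb as a share of the library total was 0.0169% of the mean of the other vehicle livers. A swap with another mouse library of the series would need a partner out of place, and 0 other mouse libraries had an Alb level that belongs to the other tissue. Adipose tissue under a liver label is a candidate explanation, as all 7 members of the fat cell list exceeded 10 times the highest other liver, among them Cfd at 13200 CPM of the library total, Fabp4 at 5820, Adipoq at 1810, Cidec at 1400 and Plin1 at 970, where no other liver exceeded 9.05 (Fabp4), although Ucp1 at 0.248 against 0 was near the floor. No biological explanation was tested, and a wrong tissue from outside the series stays open.

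IXA62 replicate 2 stood apart in kidney, low in Asns (30.6 CPM), Trib3 (4.59), Mthfd2 (14.9) and the mean log2 CPM of the PERK and ATF4 list (4.38), and in both tissues it had the lowest XBP1s list score over vehicle (0.353 in kidney and 0.333 in liver). A vehicle mouse under an IXA62 label is argued against, since the 47 UPR list members called without this library lay above the vehicle mean by a median log2 of 0.38 in it (95% interval over genes 0.30 to 0.52), where each vehicle kidney against the other vehicles was between -0.05 and 0.04, and 37 of 47 (78.7%) lay above every vehicle kidney, against 14.9 to 27.7% for a vehicle kidney, although 40 of 47 lay below the other 4 treated kidneys. That interval takes genes as independent and covers 1 library, so it leaves out the spread between mice. The measure of this test was changed after values were seen, and the share above every vehicle kidney was an earlier form of it. In kidney the counts of the 47 members had a median of 59.6% of the mean of the other 4 treated kidneys (95% interval over genes, taken as independent, 55 to 63.1). The library total was 92.9% of theirs. The library was flagged by CPM, which is already scaled for depth, so these counts restate that pattern and add no separate test of depth. A lower depth is argued against in liver, where this library was the deepest of the 5 treated ones at 32270851 counts (32.3 M). The shallow liver IXA62 replicates 3 and 4 (17.3 and 15.8 M) had the highest XBP1s scores, at 1.159 and 1.075. A relation of the liver score to depth or library quality was not tested and stays open. A weak response of 1 mouse in both tissues may account for the low values of replicate 2, as the liver library ranked 1 of 5 from the bottom. The labels do not say that a number marks 1 mouse, and the lowest of 5 would share its number by chance in 20% of cases. A weak response of 1 mouse therefore cannot be told apart from chance. Same-numbered treated liver and kidney libraries deviated from their group means with correlations of -0.138 to 0.115 across genes. Their mean was -0.025, against 0.006 for different numbers. A difference in dosing or exposure between mice stays open and untested.

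The response differed between tissues in 14 genes once the library labelled liver vehicle 1 was left out, by the interaction test of edgeR without a block. With the kidney number as a block for the kidney libraries, where samples of a number deviated together, 1 of them passed, Eif4ebp1. Without the block the liver minus kidney log2 differences were -5.35 for Slc7a5, -5.32 for Chac1, -4.85 for Trib3, -4.31 for Asns, -2.86 for Atf5, -2.46 for Pck2, -2.01 for Eif4ebp1, -1.56 for Cars, -1.51 for Atf4, -1.29 for Gars, -1.25 for Slc3a2, -1.21 for Aars and 2.02 for Acot11. Slc7a5 rose by 3.07 in kidney and was too low to be tested in liver, with 16 counts over the 3 vehicle livers and 4 over the treated ones, so part of its difference rests on those counts. The predicted gene LOC102633938 was at -4.53. Leaving out single libraries gave 0 to 35 genes, and the calls of Slc7a5, Trib3, Chac1 and Acot11 were lost without any of several of them. Without liver vehicle replicate 3 the number was 0, so every call was lost, those of Asns and Atf5 included.

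Kidney vehicle replicate 3 lay above its group in Asns (7.06 CPM), Fgf21 (0.29), Chac1 (2.53) and Trib3 (2.11) and below it in Serpina1e (6.19). Kidney vehicle replicate 2 was high in Scd1 (80.1 CPM) and replicate 4 low in Etnppl (18.8 CPM). In liver, IXA62 replicate 5 stood apart in Glt1d1 (7.74 CPM) and IXA62 replicate 2 was low in the mean log2 CPM of the red cell list (5.37).

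Other splits of the same libraries were counted for each number of genes. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Fitted on 6 libraries alone, the calls against DMSO were 4747 for IXA21, 3845 for IXA62, 2061 for IXA76, 2506 for IXA502, 3312 for IXA554, 4794 for IXA624 and 5586 for Tg, with at most 2 in any other split. The XBP1s list p against DMSO lay between 7.11e-48 (IXA554) and 5.11e-24 (IXA624), with the lowest of other splits between 1.83e-12 (Tg) and 4.27e-07 (IXA624). Against Tg it lay between 6.54e-24 (IXA21) and 2.02e-06 (IXA502), with the lowest of other splits between 9.03e-10 (IXA21) and 1.34e-05 (IXA502). IXA62 against IXA21 gave 0 genes by edgeR, with 244 in the highest other split, and IXA62 against IXA502 gave 38, with 442 in the highest other. Those 244 and 442 point to a structure of these samples. Against IXA76, IXA554 and IXA624 the real split gave 3, 25 and 31 with at most 1 in another.

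In kidney 2 of 100 drawn splits gave as many genes as the real 214, the other being 502, which placed IXA62 replicate 2 with vehicle replicates 1, 2, 4 and 5. The XBP1s list in kidney had 1 of 100 splits with as small a p (6.89e-51 against 2.18e-26 in the next). Since kidney samples of a number deviated together, the real split is compared with those that part every pair. Of these 10 were drawn, too few for a share under 0.05, with 214 genes in the real one and at most 0 in the others. In liver, 2 of 100 splits with 9 libraries gave as small a camera p for the list, the real one at 3.13e-17 and the lowest other at 9.73e-23. With 8 libraries 1 of 56 did, at 3.82e-25 with 8.92e-20 in the lowest other. Chance is not excluded by these shares, since the list call was lost with an estimated correlation (adjusted p = 0.449 and 0.257) and with fry (0.106 and 0.104). Another split of the 9 also gave a smaller p. For the number of genes the splits decide nothing, since 100 of 100 and 56 of 56 reach a real value of 0. The highest other with 9 libraries was 1. With 8 libraries it was 810, from setting the vehicle livers with IXA62 replicates 1 and 5 against replicates 2, 3 and 4, which points to a structure of these samples. For the tissue difference with 19 libraries the splits decide nothing either, since 100 of 100 reach the real 0, with 8 in the highest other. With 18 libraries chance cannot be excluded, with 5 of 100 splits as large as 14 and 480 in the highest, but these did not keep the kidney pairs. Among 100 splits that part every kidney pair it cannot be excluded either, with 7 as large and 413 in the highest, and in the fit with the kidney block 22 reached the real 1, with 69 in the highest. Those 480, 413 and 69 point to a structure of these samples.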

How the results depend on the processing

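Robust fitting, the fits with 8, 18 or fewer liver libraries, the kidney block of the tissue difference, the fits of 2 groups alone between compounds and the alternatives of the list tests against Tg were chosen after seeing the data, and the alternatives of the fixed genes and list members between compounds were run only then. Against DMSO, no alternative run moved a count of genes by over 1.5 times, and no value tested reversed. The XBP1s list kept its call against DMSO in HEK293 cells and in kidney under every alternative run. Against Tg, the XBP1s, ATF6 and PERK and ATF4 lists kept their calls under every alternative run for all 6 compounds, except the XBP1s list for IXA502 with an estimated correlation (adjusted p = 0.05748). In liver the XBP1s list call was lost with an estimated correlation (adjusted p = 0.4487 with 9 libraries and 0.2575 with 8) and with fry (0.1063 and 0.1039), and kept under the others, including without both IXA62 livers of lower depth (2.19e-23). The cause of these differences was not tested. For IXA62 against IXA21, IXA76, IXA554 and IXA624, the counts of 3, 206, 58 and 32 became 109, 542, 268 and 333 with no low-count filter and 31, 530, 268 and 186 with DESeq2. With only the 2 groups in the fit, which leaves fewer libraries to estimate the spread, they became 0, 3, 25 and 31, and the 766 against IXA502 became 38. Leaving out 1 replicate gave 1 to 102, 13 to 911, 2 to 313 and 4 to 353, and 268 to 1071 against IXA502 (766). In kidney the 214 became 448 with DESeq2 and 347 with the replicate block, and 87 to 524 without 1 replicate. The block changed no other kidney call of a named gene or a list than those given with the kidney results. In liver the 0 by edgeR became 13 with DESeq2 and 0 to 1 without 1 replicate with 9 libraries. With 8 it became 13 with no filter, 131 with DESeq2, 24 with the replicate block and 0 to 19 without 1 replicate, and it stayed at 0 without both livers of lower depth (752 at an unadjusted p under 0.05). The tissue difference with 19 libraries, 0 by edgeR, became 6 with no filter, 117 with DESeq2 and 0 to 19 without 1 replicate. With 18 it went from 14 to 8 with RLE size factors, 124 with DESeq2, 0 with the replicate block, which takes same-numbered liver and kidney libraries as 1 mouse, 1 with the kidney number as a block for the kidney libraries alone, and 0 to 35 without 1 replicate. That kidney block left 0 genes with 19 libraries (1987 at an unadjusted p under 0.05). With 18 it ended the calls of Asns, Atf5 and Chac1 (adjusted p = 0.0502), Trib3 (0.0857), Slc7a5 (0.139) and Acot11 (0.189), and it added a call of the endothelial list as lower (camera adjusted p = 0.0469, and adjusted p = 0.64 with an estimated correlation). It changed no other list call of the tissue difference. Numbers were not taken to pair samples outside kidney, with same-number correlations from -0.224 to 0.263. They were highest for IXA62 with IXA502, at 0.072 to 0.263 (mean 0.165, against -0.083 for different numbers). Outside kidney the block gave 5 genes for IXA62 against IXA21, DNAJB9 had adjusted p = 0.0528 for IXA62 against IXA624 and SQLE 0.0514 against IXA554. The PERK and ATF4 list with IXA21 had camera adjusted p = 0.0576, p53 targets with IXA21 0.0502, immediate early genes with IXA502 0.0576 and HSF1 targets with Tg 0.0553. In liver with 8 libraries Dnajb9 was at 2.10 (adjusted p = 0.0329), and several lists of other pathways and cell types changed sides in either liver fit. In the 18-library tissue difference with same-numbered libraries taken as 1 mouse, Acot11, Slc7a5, Chac1, Trib3, Asns and Atf5 had adjusted p from 0.236 to 0.699. In no such comparison did every sample correlate best with its own number, and in kidney 1 of the samples did. Among single named genes, 4279 values kept their side of the threshold without 1 replicate, 481 lost a call and 30 gained one. The shallowest liver had 15816046 counts, and what depth alone limits was not simulated. Leaving out both livers of lower depth left the count at 0 by edgeR, and the simulated recovery at 4-fold was 0% with 9 libraries and 72.7% without the library labelled liver vehicle 1.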

Other observations

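The tests of explanations in this part were chosen after the result was seen, as were the gene groups below. Levels in HEK293 cells were summed over 24 genes whose symbols have the form used for mitochondrial tRNAs. The sum was 629 ± 15.6 CPM with DMSO (SD, n = 3), 379 ± 17.8 with IXA21, 396 ± 19.5 with Tg and 533 ± 64.8 with IXA502. The other means lay between those of IXA21 and IXA502. Nuclear protein-coding genes such as TRNT1 and TRNP1 match that form too, so the sum is not of mitochondrial tRNAs alone. The sum was not tested as a set. BHLHA15 (chromosome 7, 98211427 to 98212979), below the level set for named genes, had 0 counts over the DMSO libraries and 21 (IXA502) to 41 (Tg) over each treated group, at least 6.9-fold to 13.4-fold higher against a floor of 3 counts over the group. Of the 21, IXA502 replicate 3 held 16, and without it the bound was 2.43-fold. Without DMSO replicate 1, 2 or 3 the bounds ran from 4.59-fold to 8.98-fold. In liver with 8 libraries, DESeq2 called the ER traffic genes Sec23b at 1.40, Arfgap3 at 2.57 and Tmed3 at 1.95 higher, where edgeR called 0 with 1125 at an unadjusted p under 0.05. The DESeq2 calls also held many genes of the Mup family, all higher, such as Mup17 at 1.79 and Mup1 at 1.40. These close paralogs may share reads, so the number of DESeq2 calls may count the same reads more than once.

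A set of 1173 genes passed in the same direction with all 7 treatments in HEK293 cells, 623 higher and 550 lower, of which 41 belong to the XBP1s, ATF6 or PERK and ATF4 lists. The median ratio of the Tg change to the mean IXA change was 1.1 over the 1132 others (95% interval over genes, taken as independent, 1.07 to 1.11). The 41 list genes chosen by the same calls had 1.7 (1.33 to 2.75), and 2.18 over the 15 of them with a mean IXA change no larger than the median of the others. Selection by calls against the same 3 DMSO libraries can pull a ratio toward 1. These values therefore do not decide whether the size of the response of the whole set followed ER stress. By list the ratio was 3.07 for ATF6, 2.19 for PERK and ATF4 and 1.21 for XBP1s, so a size that follows XBP1s alone stays open, as does a shared effect on other processes, both untested. A shift of the DMSO libraries alone could give the same direction everywhere and a ratio near 1, and 22.7% of the 1132 genes differed between the 7 treated groups. The share expected under such a shift or under treatment effects was not computed, so 22.7% does not decide between them. With 3 DMSO libraries they cannot be told apart.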
